A study of Arabidopsis thaliana with 6 samples.

How the data were processed

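RNA was measured in mature pollen grains of Arabidopsis thaliana, ecotype Col-0, from wild-type plants and from plants heterozygous for a NOT1 mutation (NOT1+/-). NOT1 is the scaffold subunit of CCR4-NOT, the complex that shortens the poly(A) tails of messenger RNAs. Each genotype had 3 biological replicates. Per the labels' protocols, pollen was washed out of open flowers, passed through a mesh and purified by fluorescence-activated cell sorting, with about 300000 grains per sample, and 100 ng of total RNA was amplified, labelled and hybridised to a 1-colour Affymetrix whole-transcript array strip for Arabidopsis. Grains of a heterozygous plant segregate, so each NOT1+/- sample is a mixture of grains with and without the mutant allele; the labels do not say which kind of mutation it was.

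The deposited values are intensity values on a linear scale, with 1 value per locus and array for 27827 features. Affymetrix Expression Console is named in the submitters' processing notes; its version, the summarisation, the background correction and the scaling between arrays are not given in the sources used here. The smallest value was exactly 1 on each array. Array medians lay between 12.0 and 13.1, while the 95th percentiles lay between 133 and 141 in wild type and between 193 and 202 in NOT1+/-, so the distributions had not been made identical. There were no detection calls, scan dates or strip numbers to use, so no feature could be called absent and no batch could be tested. The number of arrays limits the precision.

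The design had foreseen log2 values; because the values were linear, their log2 was taken, with no offset and no filter, and tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, trend and robust off, 1 coefficient for NOT1+/- minus wild type). P-values were adjusted by Benjamini-Hochberg over all 27827 features, and a feature was called at an adjusted p under 0.05. Fold changes are ratios of geometric means, and group values are arithmetic means ± SD of 3 arrays. Of the features, 27241 matched a locus of the reference gene table (assembly TAIR10.1), which gave a symbol to 10556 of them; other genes are given by locus code. The table served only for names and gene order. That AT1G02080 is NOT1 is background knowledge and not in that table. A total of 182 features had the same 6 values as another feature, so they measure the same probes.

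Before the data were examined, 13 gene lists were fixed by locus and 11 by keyword. The keyword lists had been meant for gene descriptions, but the table holds only symbols and synonyms, so they are thin and miss genes. Lists were tested with camera at a preset correlation of 0.01 between genes, with an estimated correlation, and with fry, and p-values were adjusted over the 24 lists. Keyword families among called genes were tested with Fisher's exact test (two-sided) against the 27241 matched features, adjusted over families and directions. Genes were named by a rule fixed at the same time: NOT1; the 15 largest rises and 15 largest falls among called genes whose 3 NOT1+/- values all lay on one side of the 3 wild-type values; up to 4 called members of each list; and the called genes among the 5 on each side of NOT1. Other genes were chosen after their values were seen, and the text says so. Some genes that the rule named, and 1 keyword family, are not reported here. The keyword list meant for pentatricopeptide repeat genes took in mostly genes named as suppressors, which share letters with the abbreviation, so it stayed among the 24 lists tested but no result is given for it as a family.

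The alternatives were the replicate number as a block, eBayes with trend and robust, array weights, 3 rescalings of the arrays, 2 filters on dim features, a floor under dim values, only features in the reference table, an unequal-variance test per feature, other set tests and leaving out each array. Adding 16 intensity units before log2, and comparing counts of calls with 10000 random lists matched on mean log2 level over all 6 arrays, were chosen after seeing the data. On simulated data for this comparison, with all 27827 features and 100 features changed at each size, limma recovered 27 of 100 at a log2 change of 1 and 82 of 100 at a log2 change of 2, with 6 false calls among 115; a simulated shifted list was found and 0 of 20 unshifted lists were called. Far fewer features changed in the simulation than the 3357 called in the data. Its adjusted threshold was therefore stricter, and its recovery does not carry over to the real comparison. Figures were drawn with matplotlib.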

Results

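Sorted mature pollen was profiled on 6 arrays, 3 from wild-type and 3 from NOT1+/- plants. Log2 values correlated across features at r = 0.926 to 0.952 between wild-type arrays, 0.965 between NOT1+/- arrays and 0.836 to 0.90 between genotypes. The first principal component held 62.7% of the variance and separated the genotypes, and the second, with 14.3%, set wild-type replicate 3 apart from the other arrays. The median SD between replicates was 0.249 log2 units in wild type and 0.221 in NOT1+/-. Genes are not independent replicates, so these correlations describe the arrays only.

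The level of NOT1 (AT1G02080) was examined first, since it checks the labels. Its intensity was 48.5 ± 2.2 in wild type and 31.0 ± 2.11 in NOT1+/- pollen (SD, n = 3 arrays each), and all 3 NOT1+/- values lay below all 3 wild-type values. The log2 fold change was -0.65 (SE 0.15, 95% interval -0.998 to -0.30), or 63.8% of the wild-type level, with a limma adjusted p of 0.029. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. The call ended when any 1 of the 6 arrays was left out (adjusted p 0.053 to 0.118) and with median centring (0.055). The direction did not change, although leaving out an array could not have reversed it, as the groups did not overlap. Where on the gene the mutation and the probes lie is not given in the sources used here.

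Of the 5 genes on each side of NOT1, 2 were called, both lower and both on the same side. SBI1 (AT1G02100) had an intensity of 81.8 ± 3.20 in wild type and 44.7 ± 5.22 in NOT1+/- (log2 fold change -0.88, SE 0.16, limma adjusted p = 0.0096). AT1G02110 had 33.2 ± 1.32 and 14.3 ± 1.3 (-1.22, SE 0.15, adjusted p = 0.0015). FUS5, which lies between NOT1 and SBI1, had a log2 fold change of 0.08 (adjusted p = 0.81), and VAD1, the next gene after AT1G02110, had -0.58 (adjusted p = 0.068).

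Across the array, NOT1+/- pollen differed from wild type mainly by genes that were higher. Limma called 3357 of 27827 features, 2461 higher and 896 lower in NOT1+/-. With at least 2-fold change there were 1792 higher and 209 lower, and with at least 4-fold change 747 higher and 3 lower. Many of the rises reached high signal: 1394 features had a mean above 200 in NOT1+/- and 992 in wild type, and 462 of the former had been called at least 2-fold higher. The median log2 fold change over all features was -0.10. The share of higher calls, 73.3%, depended on the scaling, with 52.5% after quantile normalization and 60.2% after centring on the 75th percentile; among calls of at least 2-fold it was 89.6%, and 71.7% after quantile normalization. The unequal-variance test per feature called 1460, and leaving out NOT1+/- replicate 1 or 2 gave 2080 and 2169 calls. Lower calls numbered 586, 410 and 596 without wild-type replicates 1, 2 and 3, and 258 and 315 without NOT1+/- replicates 1 and 2.

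**Figure D1:**
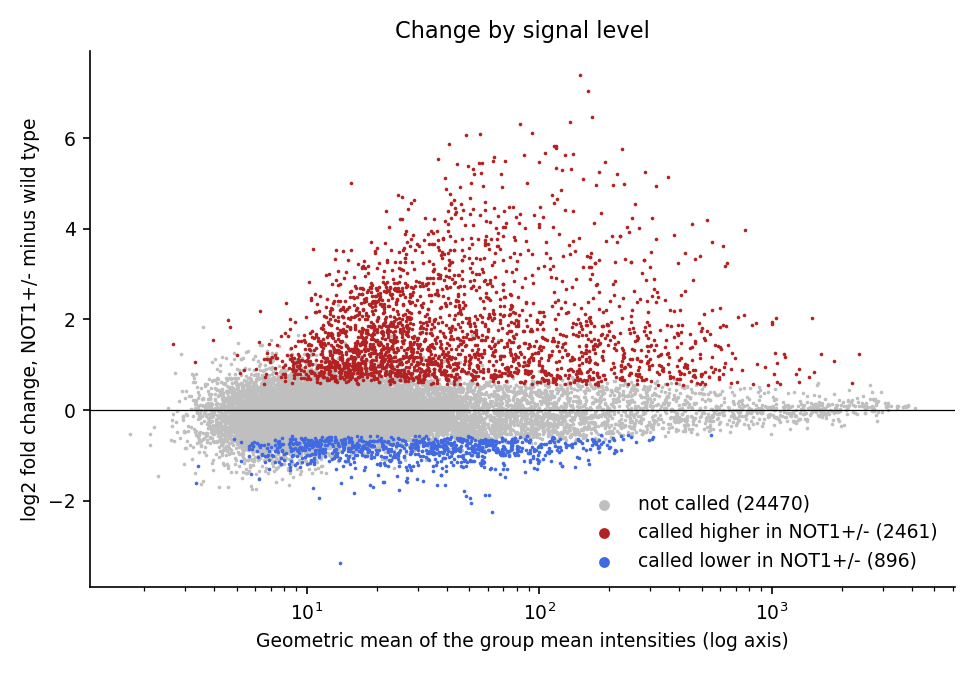
Each point is 1 feature, with the geometric mean of the group mean intensities on a log axis and the log2 fold change (NOT1+/- minus wild type) on the vertical axis. The 2461 features called higher reach a log2 fold change of 7.39, while the 896 called lower end at -3.38.

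The largest rises took genes with a low wild-type signal to among the brighter features. AT1G47980 went from 11.5 ± 1.28 to 1933 ± 245 (log2 fold change 7.39, SE 0.18, limma adjusted p = 2.89e-06), and LCR25, a cysteine-rich peptide of the defensin-like class, from 14.03 ± 0.836 to 1858 ± 198 (7.04, SE 0.16). AT4G02140 rose by a log2 fold change of 6.48 and LHT2, an amino acid transporter, by 6.35, although its wild-type arrays were spread widely (16.8 ± 14.3). The remaining 11 of the 15 largest rises were AT1G04670, AT5G46940, AT5G24610, AT3G60520, SCRL27, BCA3 (a carbonic anhydrase), AT3G29040, AT1G54620, AT5G01760, GPX6 (a glutathione peroxidase) and AT1G66360, with log2 fold changes between 5.64 and 6.32. A total of 234 features rose at least 10-fold. Several of these wild-type values, such as 11.5 for AT1G47980 and 5.46 for SCRL27, lay below the array medians of 12.0 to 13.1. No detection calls separated such values from background, and the background correction is not known. A fold may therefore be too small or too large, and the sizes of these rises and their order are uncertain.

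Falls were smaller. AT5G54460 went from 47.4 ± 27.7 to 4.07 ± 0.112 (log2 fold change -3.38, SE 0.38, limma adjusted p = 7.38e-04), with a wide spread in wild type and a NOT1+/- level below the array medians, so the size of this fall is uncertain too. AT1G56660 fell from 137 ± 30.6 to 28.5 ± 6.13 (-2.26) and UMAMIT34, of an amino acid transporter family, from 103 ± 1.71 to 25.2 ± 4.17 (-2.05). AT1G02380, PRMT4B (a protein arginine methyltransferase), PSK6 (a phytosulfokine precursor), AT4G30490, HSFA6A (a heat shock transcription factor), BPS3, AT2G13125, RABA1c, FER3 (a ferritin), AT4G18070 and AT2G24460 had log2 fold changes from -1.95 to -1.65. Of the 209 features called with a fall beyond 2-fold, 26 had a 95% interval wholly below a log2 fold change of -1. These counts depended on the scaling and on dim values: they were 613 and 98 after quantile normalization, 363 and 32 after centring on the 75th percentile, and 30 and 7 with 16 units added before log2, a setting chosen after the data were seen; among features above the 75th percentile of level 126 fell beyond 2-fold. A one-sided limma test against -1 called 0 features after adjustment.

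Within the CCR4-NOT list, 4 of 28 members rose, NOT1 fell and 23 did not pass (adjusted over the list alone, 4 higher and 3 lower). AT2G32070 and AT5G10960, deadenylases of the CAF1 family, had log2 fold changes of 2.71 (SE 0.21) and 2.29 (SE 0.18), and AT5G10960 went from 51.4 ± 3.97 to 252 ± 39.1. The wild-type mean of AT2G32070, 8.97, lay below the array medians, so the size of its rise is uncertain. AT3G58580 and AT3G20800 rose by 0.83 and 0.71. In the list for mRNA decapping and decay, VCS, a decapping scaffold, rose by 0.85 and AT1G79090 by 0.62, and the other 23 of 25 did not pass (1 higher and 0 lower, adjusted over the list alone). AT3G58580 and AT1G79090 lost their calls under quantile normalization and centring on the 75th percentile, and AT3G20800 and VCS under quantile normalization. In the list for poly(A) binding and translation initiation, 4 of 14 rose and 1 fell (5 and 1, adjusted over the list alone): the cap-binding protein EIF4E had 2.21 (SE 0.21), LSP1 0.83, PAB6 0.76 and EIF4G 0.63, against -0.62 for eIFiso4G1. The wild-type mean of EIF4E, 7.61, also lay below the array medians, so the size of its rise is uncertain too. LSP1, PAB6 and EIF4G lost their calls under quantile normalization and centring on the 75th percentile. Under quantile normalization the balance turned in all 3 lists, with 2 higher and 4 lower in the CCR4-NOT list, 0 and 4 in the decay list and 1 and 2 in the poly(A) list; after centring on the 75th percentile the counts were 3 and 3, 1 and 0, and 1 and 1. Several of these counts fell when 1 array was left out, which also leaves fewer samples. In the CCR4-NOT list 2 rises were called without wild-type replicate 1 or 2 or NOT1+/- replicate 1 or 2, and the fall of NOT1 was lost when any 1 array was left out. In the decay list 0 were called without wild-type replicate 1 or NOT1+/- replicate 2, and 1 without each of the others. In the poly(A) list 1 rise was called without wild-type replicate 1 or 3 or NOT1+/- replicate 2 or 3, 2 without wild-type replicate 2 and 3 without NOT1+/- replicate 1, and its fall was lost when any 1 array was left out.

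Genes of pollen function were among the rises. In the pollen tube list, 11 of 42 rose and 0 fell, with 31 not called (11 and 1, adjusted over the list alone). The list was bright, with a median wild-type intensity of 732. Over all features 2461 of 27827 were called higher, and 780 of 2783 in the highest decile of mean log2 level over all 6 arrays. A share like that of the list is therefore not particular to pollen tube genes. None of the 3 lists in this paragraph was compared with random lists matched on level. The plasma membrane proton pump HA9 went from 23.9 ± 3.21 to 565 ± 91.6 (log2 fold change 4.56, SE 0.19) and HA6 from 82.9 ± 9.15 to 326 ± 66.7 (1.96, SE 0.20), while ROPGEF9, an activator of ROP GTPases, had 1.25 and AT2G41970 had 1.19. Among 17 pollen transcription factors 6 rose and 1 fell (6 and 1, adjusted over the list alone) and LBD27 was among the rises (log2 fold change 4.16, SE 0.27). In the sperm cell list 7 of 20 rose and 1 fell (7 and 1, adjusted over the list alone). The zinc finger genes DAZ1 and DAZ2 had 2.24 (SE 0.16) and 1.81 (SE 0.18), DAN1 had 1.48 and DAU2 1.17. Under quantile normalization the median of each of these 3 lists was below 0. Calls then numbered 7 higher and 9 lower among the pollen tube genes and 5 and 6 among the transcription factors. The sperm genes had 5 and 3. Quantile normalization lowers bright features in NOT1+/- arrays by construction, as the upper percentiles were higher there. The median log2 fold change of the sperm list, 0.27, became 0.086 without NOT1+/- replicate 3; over the wild-type mean, the list's median was 0.041, 0.20 and 0.65 in NOT1+/- replicates 1, 2 and 3. The rises in the sperm list numbered 4 without wild-type replicate 2 or NOT1+/- replicate 2, and its 1 fall was lost without NOT1+/- replicate 1. The 1 fall among the transcription factors was called only with all arrays or without wild-type replicate 1.

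Stress genes moved in both directions. In the heat shock and folding list 4 of 29 rose and 9 fell (5 and 11, adjusted over the list alone). The rises were the endoplasmic reticulum (ER) chaperones BIP1, from 25.4 ± 5.71 to 251 ± 73.0 (log2 fold change 3.28, SE 0.27), BIP2 (2.92, SE 0.29) and BIP3 (2.90, SE 0.19), and ATERDJ3A, the smallest. The falls included HSP17.6II (-1.27, SE 0.32) and, outside the naming rule, HSP90.1 (-1.14, SE 0.20), HSP17.4 (-1.02, SE 0.16) and HSP101 (-0.995, SE 0.16), all cytosolic heat shock proteins. By keyword, 9 of 60 heat shock genes were called lower, 15.0% against 3.25% of all matched features (Fisher's exact test, odds ratio 5.29, adjusted p = 0.0014), and 5 without NOT1+/- replicate 1, while SHD, HSC70-1 and HSBP of that family rose. Without NOT1+/- replicate 1 the heat shock and folding list also had 5 falls. Fisher's exact test treats genes as independent. Camera called neither the keyword family (adjusted p = 0.24) nor the heat shock and folding list, which holds the BiP rises (0.15). With an estimated correlation both had an adjusted camera p of 0.52. Fry, which does not compare a list with other genes, called both lower (adjusted p = 0.015 and 0.036). In the wound, touch and defence list, TCH2 (1.60), JAZ1 (1.26) and JAZ8 (1.25) rose and 21 of 24 did not pass (4 higher and 1 lower, adjusted over the list alone). The wild-type means of TCH2 and JAZ8, 9.73 and 8.13, lay below the array medians, so these sizes are uncertain.

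**Figure D2:**
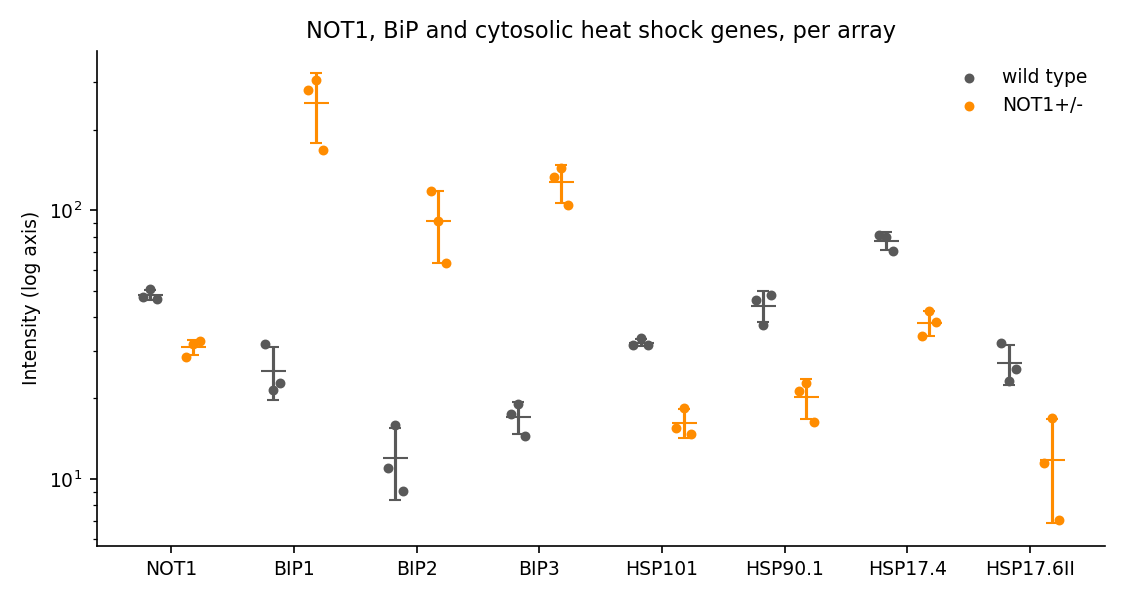
Intensity on a log axis for NOT1, the 3 BiP genes and 4 cytosolic heat shock genes, with 1 point per array and bars for the mean ± SD of 3 arrays. BIP1 averaged 25.4 in wild type and 251 in NOT1+/- pollen, while HSP101 averaged 32.3 and 16.3.

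Markers of other tissues were low and none was called higher in the fit to all features. When only features above the median level were tested, 1 of 5 floral organ genes, PI (AT5G20240), was called higher (log2 fold change 0.49, SE 0.15, adjusted p = 0.041, against 0.115 over all features); it falls outside the naming rule. Photosynthesis genes had a median intensity of 10.3 in wild type and 9.14 in NOT1+/-, below the array medians, and 2 of 26, LHCA1 and CAB2, fell. SHP1 was the only call among 12 floral organ genes and EXL4 the only one among 22 tapetum and pollen coat genes, both lower; none of these 4 calls held when the p-values were adjusted over the list alone, after quantile normalization or after median centring. Without 1 array, 1 photosynthesis gene was called without wild-type replicate 1 or NOT1+/- replicate 1 and 0 without each of the others, the floral call held only without NOT1+/- replicate 3 and the tapetum call only without wild-type replicate 3. In the list for replication and division, the cyclin-dependent kinase inhibitor KRP6 (1.99, SE 0.26) and the replication licensing factor CDT1A (0.94, not called after quantile normalization) rose and 21 of 23 did not pass (2 and 0, adjusted over the list alone), while 1 was higher and 3 were lower after quantile normalization. In the small RNA and DNA methylation list, the methyltransferase MET1 (-0.92) and the Argonaute AGO9 (-0.86) fell and 30 of 32 did not pass (0 and 2, adjusted over the list alone), with 1 fall when any 1 wild-type array was left out and 0 without NOT1+/- replicate 1 or 2.

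Among the keyword lists, 14 of 89 defensin-like genes rose and 1 fell, with LCR33 at 5.48, LCR1 at 5.31 and LCR5 at 5.25 after LCR25 (Fisher's exact test for rises, p = 0.037, adjusted p = 0.21). Against 10000 random lists matched on mean level, a comparison chosen after the data were seen, the median was 6 rises and 0.07% of the lists had as many as 14. Cytochrome P450 genes were scarce among the rises, with 1 of 232 (CYP79A4P; 2 without wild-type replicate 1) against 8.88% of all matched features (odds ratio 0.044, adjusted p = 3.96e-07). Their median wild-type intensity was 10.6. By decile of mean log2 level over all 6 arrays, 17 of 2783 features rose in the lowest and 780 of 2783 in the highest. That level includes the NOT1+/- arrays, so a rise itself lifts a feature to a higher decile. The trend is therefore partly built in. In random lists matched on the same level the median was 9 rises, and 0.07% of the lists had as few as 1. Transporters counted 35 higher and 13 lower of 348, with AAP5 (4.39), SULTR1;3 (4.31) and PHT1;7 (4.01) next to LHT2. Ribosomal protein genes counted 7 higher and 1 lower of 48, led by RPS6 (1.89). Protein kinases counted 18 and 8 of 278, with CPK15 at 2.42 and MPK12 at 2.18. F-box genes counted 5 and 0 of 31 (FBS1, 2.61), histones 4 and 0 of 31 (HTA7, 1.87) and genes with names of pectin enzymes 2 and 1 of 31 (PMEI2, 4.03, and AT3G07830, 3.86, against PGIP2, -1.26), where PMEI2 and PGIP2 are inhibitors of such enzymes. None of these last 6 families passed Fisher's exact test after adjustment. RPS6, CPK15, MPK12 and FBS1 had wild-type means of 9.79, 6.47, 6.10 and 7.47, below the array medians, so the sizes of their rises are uncertain. After quantile normalization protein kinases counted 13 higher and 24 lower and transporters 33 and 23, after centring on the 75th percentile protein kinases counted 15 and 14 and histones 3 and 4, and among features above the 75th percentile of level 0 of 6 ribosomal protein genes were higher and 4 lower. Falls of transporters and protein kinases were fewer without most single arrays, which also leaves fewer samples. Transporters had 6, 7, 4, 7 and 5 without wild-type replicates 2 and 3 and NOT1+/- replicates 1, 2 and 3. Protein kinases had 3, 5, 3 and 2 without wild-type replicates 2 and 3 and NOT1+/- replicates 1 and 2. Ribosomal protein genes had 4 rises without NOT1+/- replicate 1, and their fall was called only with all arrays or without NOT1+/- replicate 3. Without 1 array, falls in the defensin list numbered 0 (wild-type replicate 3 or NOT1+/- replicate 3) or 2 (wild-type replicate 2), in the pectin list 0 (NOT1+/- replicate 1 or 3) or 2 (wild-type replicate 3), among F-box genes 1 (wild-type replicate 1 or 2) and among histones 2 (wild-type replicate 3) or 1 (NOT1+/- replicate 1).

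As whole lists, camera called 0 of the 24 after adjustment and 7 at an unadjusted p under 0.05. The lowest adjusted p, 0.0501, was shared by the pollen tube and sperm cell lists, with 0.52 and 0.64 as adjusted p when the correlation was estimated. Camera called 3 lists without wild-type replicate 3 (sperm cell and pollen tube upward, cytochrome P450 downward), 2 without NOT1+/- replicate 1 (sperm cell and pollen tube) and 1 without NOT1+/- replicate 2 (sperm cell), all at the preset correlation. With all arrays and an estimated correlation the adjusted p of the cytochrome P450 list was also 0.52 (p = 0.217). Fry, which does not compare a list with other genes, called 12 lists for movement in one direction and 22 for change in either direction. Among the lists reported, median and mean differed in sign for the wound, division, pectin, defensin, F-box, histone and transporter lists, and only for pectin did camera point down.

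**Figure D3:**
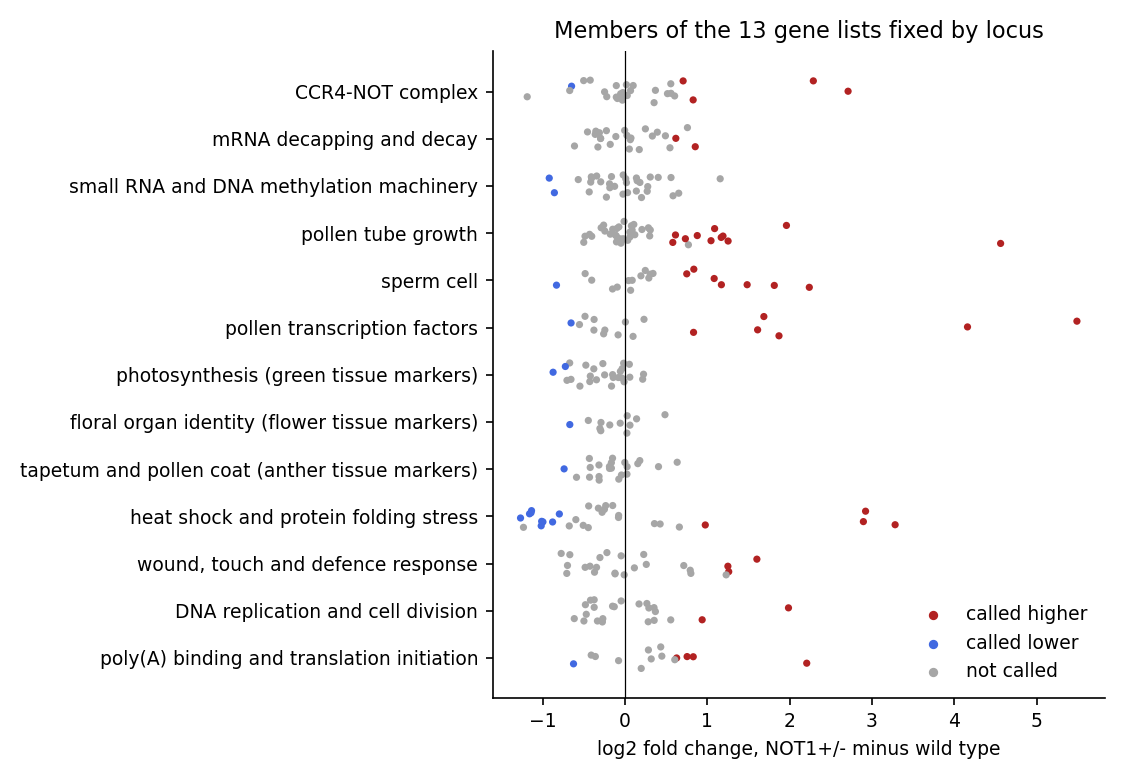
Log2 fold change (NOT1+/- minus wild type) of each member of the 13 lists fixed by locus, 1 point per gene, spread vertically within a list for legibility; red and blue mark genes called higher and lower. In the heat shock list 4 members were called higher and 9 lower, and no member of the photosynthesis, floral or tapetum lists was called higher.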

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

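Adding 16 units before log2 was chosen after the data were seen; all other alternatives were planned. The sign of every one of the 104 named genes other than NOT1 held in all 17 refits that tested it. Only the rescalings of the arrays could have reversed a sign, so the other refits say nothing about direction. In all 2461 higher and 896 lower calls the values of the 2 genotypes did not overlap. Of 1730 refitted values, 1583 stayed on the same side of the threshold, with 147 losing the call. For the 24 lists, 388 of 405 values stayed on their side and 15 gained a call. The list statistic is the mean z-score of the list minus that of other features. Under quantile normalization it became -0.28 for pollen tube growth and -0.094 for pollen transcription factors, so camera's direction reversed. The upper percentiles were higher in NOT1+/- arrays, so making the distributions identical lowers bright features there by construction. Both lists were bright, with median wild-type intensities of 732 and 215. How much of the reversal this accounts for was not tested.

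Whether the numbers 1 to 3 pair the samples was not settled. Deviations from the group means correlated at 0.11, 0.13 and -0.01 for equal numbers. Wild-type replicates 1 and 2 were closest to their own number, and wild-type replicate 3 was not. With the replicate block 2718 features were called, 555 of them lower, and the adjusted p of NOT1 was 0.070 at a log2 fold change of -0.65. Without 1 array, which leaves fewer samples, calls ranged from 2080 to 2959 and lower calls from 258 without NOT1+/- replicate 1 to 711 without NOT1+/- replicate 3. Without 1 array NOT1 had log2 fold changes from -0.68 to -0.59, and 0 to 3 lists were called.

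Lower calls, 896 as reported, numbered 1458 with trend and robust, 1991 after quantile normalization, 571 after median centring, 1460 after centring on the 75th percentile, 1515 and 1363 among features above the median and the 75th percentile of level, 1399 with the floor and 1490 with 16 units added. Lower calls of at least 2-fold, 209 as reported, numbered 613 after quantile normalization, 363 after centring on the 75th percentile, 126 above the 75th percentile of level and 30 with 16 units added. Adding 16 units, which shrinks dim changes by construction, gave 1193 calls of at least 2-fold, 1163 of them higher. Falls with an interval below -1, 26 as reported, numbered 98 after quantile normalization and 7 with 16 units added. Median centring left NOT1 at -0.57. The unequal-variance test called 1460, with 1229 higher and 231 lower. Lists called by camera numbered 2 with trend and robust, 2 after median centring, 1 above the median level, 1 above the 75th percentile of level, 1 with the floor and 2 with 16 units added; fry called 12 and, for either direction, 22. Keyword families past the threshold, 2 as reported, numbered 4 after quantile normalization and 1 above the 75th percentile of level. Unless the construction is named, the cause was not tested. Without detection calls, signal over background cannot be judged, and changes of features near or below the array median are uncertain.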

Other observations

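The ER, SCR-like, galacturonosyltransferase and mitochondrial groups, the tests of tissue, division stage and signal level, the rescaled intervals and the lists matched on level were chosen only after results had been seen. A list of 22 genes of ER folding and quality control, without BiP, was written after the BiP rises were seen and before its own values were: 14 rose and 0 fell in each of the 3 rescalings and without any 1 array. SHD, the ER HSP90, went from 8.92 ± 0.917 to 293 ± 66.0 (log2 fold change 5.01, SE 0.21; its wild-type level lay below the array medians, so the size is uncertain), the calreticulins CRT1a and CRT1b had 3.94 and 3.23, the calnexin CNX1 3.67 and the disulfide isomerases UNE5 and PDIL2-3 3.62 and 3.61 (limma adjusted p of 7.46e-06 to 6.74e-05). The wild-type means of CRT1a, CRT1b and PDIL2-3 (6.84, 11.4 and 10.5) also lay below the array medians. PDIL2-2, CRT3 and BAG7 had log2 fold changes of 0.12, -0.12 and -0.18 and were not called.

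Among 356 symbol stems with at least 6 features, 6 of 712 Fisher's exact tests passed adjustment. SCR-like peptides (SCRL), small cysteine-rich proteins, were higher for 12 of 27 (adjusted p = 7.84e-04), with SCRL27 at 5.87, SCRL23 at 5.46 and SCRL25 at 5.33. Galacturonosyltransferases (GAUT), which build pectin, were higher for 8 of 13 (adjusted p = 0.0012), led by GAUT2 at 2.84 and GAUT11 at 2.56; only 4 passed without NOT1+/- replicate 1 and 5 without wild-type replicate 1, wild-type replicate 2 or NOT1+/- replicate 2. HSP genes were lower for 8 of 23, and CYP, MIR and MYB genes were scarce among the rises (1 of 229, 0 of 174 and 0 of 120). The HSP falls and the CYP rise are calls already counted in the keyword families above, so these 2 stems are not separate findings. Random lists matched on mean level had as few rises in 0.04%, 0.74% and 0.3% of 10000 draws for CYP, MIR and MYB. They had as many rises in 0% for SCRL, 0.11% for GAUT and, for the mitochondrial features below, 0%. Of 92 features whose locus code has the mitochondrial prefix, 33 were higher and 3 lower, with 1 lower without wild-type replicate 1 or 2 and 0 without each other array (35.9% higher against 8.75% of other features, Fisher's exact test, p = 7.97e-13). Of the 33, 12 had the same values as another feature, so their signal cannot be assigned to 1 locus; with each set of identical values counted once, 32 of 90 were higher (Fisher's exact test, p = 2.11e-12). Fisher's exact test and the random lists treat features as independent, although features of 1 genome can move together. No test that allows for correlation was run for the mitochondrial features or the SCRL and GAUT stems. The p-values of these groups may therefore be too small. ATMG00160 went from 89.5 ± 4.61 to 1023 ± 266. Nuclear loci from AT2G07660 to AT2G07799 were higher for 27 of 87, some of these features share values, and 1 of 15 plastid features was higher. Over the 1792 features called at least 2-fold higher, the median log2 rise over the wild-type mean was 1.93, 1.90 and 1.60 in NOT1+/- replicates 1, 2 and 3.

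Most changes of at least 2-fold were rises. Green, floral or anther tissue in the NOT1+/- sort is argued against, since 0 of 60 markers of these tissues were called higher in the fit to all features (PI alone, at 0.49, was called when only features above the median level were tested) and the abundant photosynthesis transcripts had a median log2 fold change of -0.20; the sort also selects intact grains. Scaling between arrays may account for part of the excess, as the share of rises among such calls fell to 71.7% under quantile normalization, between the 60% and 80% set beforehand as bounds. Grains at an earlier stage stay open: 8 mitotic genes had a median log2 fold change of -0.16, but 6 of them were dim, which excludes nothing. The real split called 3357 features and the highest of the other splits 0, and only 1 of the 10 splits called as many, but 10 splits are too few to give a share under 0.05; the genotype itself remains an untested explanation.

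Falls beyond 2-fold would be unexpected if RNA were lost only in the mutant grains. Scaling between arrays is not settled as a cause of such falls. Of the 26 falls with a 95% interval below -1, 20 kept it under all 3 rescalings. Of the 209 called falls, 141 stayed beyond 2-fold in all 3. Quantile normalization and centring on the 75th percentile, however, raised the number of such falls to 613 and 363, so keeping falls there is weak evidence. Only median centring worked against falls, and it moved the median log2 fold change by little, from -0.10 to -0.026. The one-sided test called 0 features past a log2 fold change of -1, and 0 under each of the 3 rescalings, but it also recovered 0% of 200 simulated 4-fold falls and decides nothing. The 26 intervals are not adjusted for the number of features, so whether any fall truly passed 2-fold cannot be told apart from RNA lost only in the mutant grains.

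BiP genes rose while cytosolic heat shock genes fell. A trend of fold change with signal level is argued against for the falls. The 24 heat shock list members other than BiP, BZIP60 and ATERDJ3A, called or not, had a median log2 fold change of -0.55. This lay at percentile 0 of 10000 random lists of like signal. Random lists treat genes as independent, so the percentile may be too extreme for genes that move together. The 24 members are not all cytosolic heat shock proteins. DREB2A, HSFA2 and HSFA7A, for example, are transcription factors, so the percentile is 1 for a mixed list. The percentile was also 0 for the 8 called heat shock genes among the 24, which were picked by their falls. Cross-hybridisation between the BiP genes stays open for how many of the 3 rose. The ER list without BiP shifted upward (camera p = 4.31e-17, and p = 0.045 with an estimated correlation), which had been set beforehand as evidence against it, but that bound was wrong because the list holds no BiP probes. HSC70-1, a constitutive cytosolic chaperone, rose by 1.58, so the contrast does not cover every cytosolic chaperone, and the genotype itself remains an untested explanation.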
